A study of Mus musculus with 8 samples.

How the data were processed

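RNA was measured by sequencing in 8 samples of visual cortex from adult C57BL/6J mice. An LNA oligonucleotide, a short nucleic acid with chemically locked nucleotides that binds a microRNA and blocks it, had been injected into the cortex on postnatal day 122. Tissue was taken on postnatal day 129, 7 days later. The 4 control samples received an oligonucleotide of scrambled sequence and the 4 treated samples one complementary to miR-29a. Per the labels' protocols, total RNA was extracted with a phenol and guanidine reagent and made into libraries with a kit that does not mark the strand of origin, so reads from a gene and an antisense partner cannot be told apart. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Because 6 of the 8 libraries held transcripts of both sexes, a sample may be a pool of animals, and n = 4 counts samples.

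The deposited table holds FPKM, fragments scaled to transcript length and to the number of mapped fragments, with 1 value per gene row and library. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie and Cuffnorm were used with the mouse genome build mm10. The order of these steps, the gene annotation, the filters and the Cuffnorm scaling setting are not given in the sources used here. The table has 24883 rows, of which 537 repeat a symbol already present, and these were kept as separate rows.

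No read counts or total depths were used here. Relative depth was estimated from the spacing of low values: among genes with a mean under 0.2 FPKM, 41.3% to 51.9% of the ratios to scrambled replicate 1 lay within 0.02 log2 units of a ratio of small whole numbers, against 16.3% to 17.1% on a shifted grid. The spacing gave relative depths of 0.973 to 1.157, so the libraries were of similar depth. It was not regular enough to recover whole reads for each gene. FPKM sums were not compared between libraries, because very short RNAs dominate them: Mir3082 alone held 12580200 FPKM in anti-miR-29a replicate 4, 96.8% of that library's sum. The FPKM rows of short RNAs can therefore not be read as their abundance.

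Genes with a mean of at least 0.5 FPKM over the 8 libraries were tested, which left 13912 rows. Values were taken as log2(FPKM + 0.1) and fitted with limma 3.58.1 in R 4.3.3, with group as the only term and a variance trend. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. For 12 single genes chosen in advance an exact two-sided permutation test over all 70 relabellings was added, whose smallest possible p is 0.0286.

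The gene lists were fixed before the data were examined, and 33 of them had at least 5 tested members. Each was compared with all other tested genes by camera with a preset inter-gene correlation of 0.01. An estimated correlation and fry served as alternatives. The direction of a list is that of camera where the list passes in either setting, and otherwise the sign of its median. This last convention was set after the alternatives had first been computed. Genes named in the text are the 10 of smallest p among those with a mean of at least 1 FPKM and no overlap between groups, because fewer than 10 passed. Up to 4 members of smallest p from each list and the 12 single genes complete the rule. Genes outside it are said to have been chosen after their values were seen. Some list members are not reported here.

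Gene positions, transcript lengths and 3' UTRs came from GENCODE M21, which uses the same assembly as mm10. Of 13822 tested symbols 99.3% matched it, 412 of them through an older symbol. The 3' UTR was the longest one among a gene's protein-coding transcripts, a restriction set before any seed site result was computed. A seed site was a match to TGGTGCT, the complement of miR-29 positions 2 to 8. The set of genes with a site was tested with camera against searched genes without one, and the difference of medians was ranked among all 140 rearrangements of the same 7 bases. A matched difference compared each gene with a site with the median of genes without one in the same class, with 10 classes of 3' UTR length and 5 of expression cut at quantiles.

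Alternatives set in advance were pseudocounts of 1 and 0.01, no filter and a mean of at least 5 FPKM, quantile normalization, median centring, sample weights, robust empirical Bayes, the replicate number as a block, each library left out in turn, and other site definitions. Chosen after seeing the data were leaving out genes without an annotated transcript of at least 200 nt, removing a smooth trend on transcript length and GC content from each library, a covariate for Y-linked expression, and subsets of the target list.

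The fit was tested on simulated data with 200 changed genes in each of 10 runs over the 13912 rows. It recovered 41.5% of genes shifted by 0.5, 68.4% of those shifted by 1 and 93.5% of those shifted by 2 on the log2 scale, and 4.9% of its calls were false. Noise was drawn independently for each gene and shifts of all sizes were planted together, so these shares need not hold for the real libraries. With a within-list correlation of 0.2 and no change, camera at the preset correlation called a mean of 8.15 of the 33 lists, against 0 with an estimated correlation. With the same correlation and the activity list shifted by 0.5, the estimated correlation called that list in 40% of 20 runs, so a list that misses with it is not shown to be unchanged. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.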

Results

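Gene expression was measured by RNA sequencing in the visual cortex of adult mice, 7 days after an intracortical injection of a locked nucleic acid oligonucleotide. In 4 libraries the oligonucleotide had a scrambled sequence, and in the other 4 it was complementary to miR-29a, a microRNA that the series links to the limits on plasticity in the adult cortex. Each library listed 12538 to 12769 gene rows at 1 FPKM or more, and spacing of the low values put the relative depths between 0.973 and 1.157 of scrambled replicate 1. Pearson correlations of log2 values were 0.932 to 0.963 within groups and 0.931 to 0.957 between them. The first principal component was computed over genes with a mean of at least 1 FPKM and a transcript of at least 200 nt. It held 19.9% of the variance and placed every anti-miR-29a library (8.62 to 15.8) above every scrambled library (-33.9 to 0.789). Scrambled replicate 2 stood far from the rest on it, at -33.9 against -10.6 to 0.789 for the other scrambled libraries. Components 2 and 3 held nearly as much, 17.4% and 15.6%. Scrambled replicate 3 stood apart on component 2 at -34.1, and anti-miR-29a replicate 3 on component 3 at 31.1. Group is therefore not shown to be the main source of variation. The rows of the miR-29 precursors themselves were listed at 0 in all 8 libraries, so the block of the microRNA has no direct readout here.

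The comparison of anti-miR-29a with scrambled libraries asked which transcripts respond when miR-29a is blocked. Bdh1, a mitochondrial enzyme of ketone body metabolism, rose from 12.6 ± 1.29 to 21.1 ± 1.33 FPKM (SD, n = 4 per group), a log2 change of 0.74 with a standard error of 0.085 (limma, adjusted p = 0.0384). Its gene lies on chromosome 16 at 31422280 to 31458901 (mm10), and its 3' UTR of 1807 nt holds 4 matches to the miR-29 seed. Snora23, a small nucleolar RNA on chromosome 7, was the other gene to pass (adjusted p = 0.0024). It read 1.97, 3.90, 3.87 and 1.97 FPKM in the scrambled libraries and was listed at 0 in the anti-miR-29a libraries. These scrambled values lie at 2 levels, the higher about 2 times the lower, as 1 and 2 reads per library would give, so this call is not a firm one and the smallest p of the comparison rests on it. No fold is stated against a group at 0, and without genes that lack an annotated transcript of at least 200 nt, an alternative chosen after seeing the data, limma called 0 genes and 1507 had an unadjusted p under 0.05.

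The next 8 genes by p missed the threshold after adjustment over all 13912 tested rows, although in each of them all 4 anti-miR-29a libraries lay above all 4 scrambled ones. Dnmt3a, the de novo DNA methyltransferase and a reported miR-29 target, read 9.0 ± 0.727 FPKM in scrambled and 14.6 ± 1.70 in anti-miR-29a libraries, a log2 difference of 0.69 (limma, adjusted p = 0.0749; exact permutation p = 0.0286, the smallest that 70 relabellings can give). Col26a1, a collagen chain, read 3.29 ± 0.602 and 6.35 ± 0.404 FPKM, and Sik1, a salt-inducible kinase gene, 1.88 ± 0.359 and 5.39 ± 1.54 FPKM. Differences of 0.56, 0.37, 0.66, 0.43 and 0.78 log2 units were measured for Dcakd, Ankrd13b, Tmem229b, Dnajb5 and Ccdc28b. Adjusted p was 0.0749 for these genes except Ccdc28b and Sik1, where it was 0.0821.

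**Figure D1:**
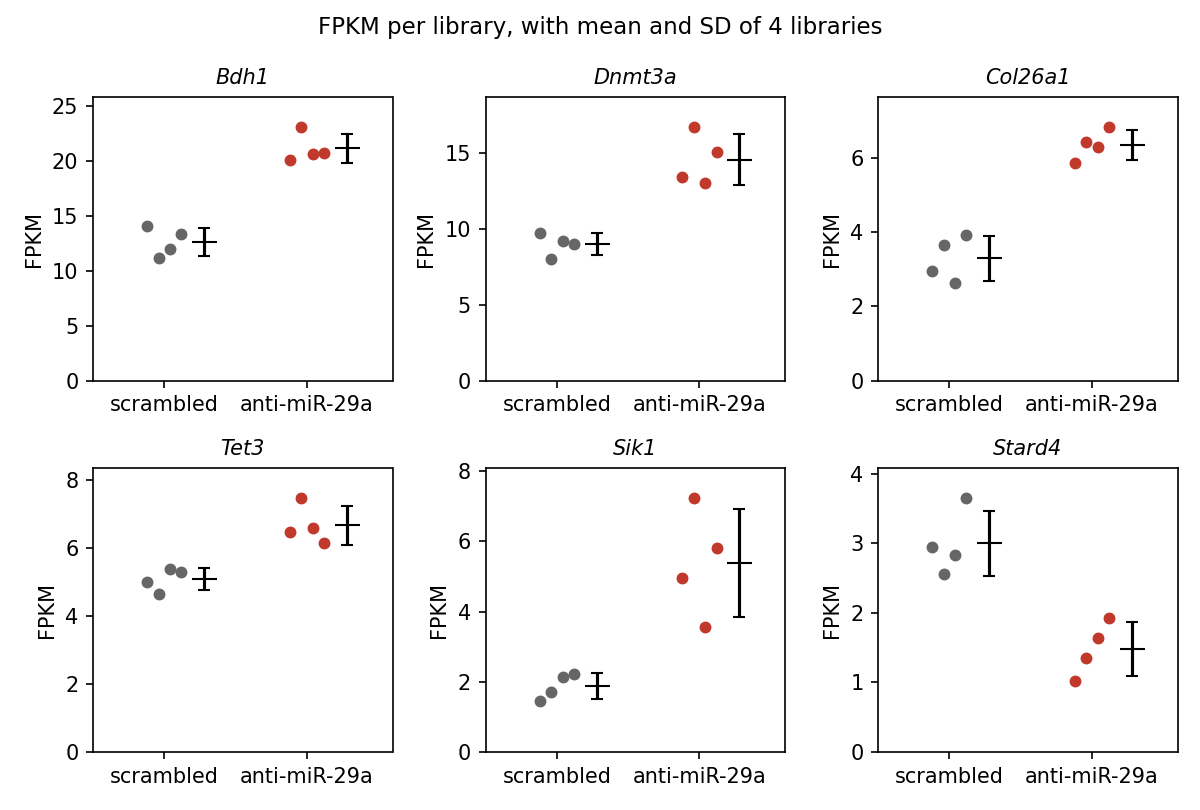
FPKM of 6 genes in each of the 8 libraries, scrambled in grey and anti-miR-29a in red, with the mean and SD of 4 libraries beside each group. Bdh1 passed the test over all genes, with a scrambled mean of 12.6 and an anti-miR-29a mean of 21.1 FPKM, and the other 5 genes did not.

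At an unadjusted p under 0.05 limma counted 1049 genes higher and 443 lower in anti-miR-29a libraries, 1492 in all, where 696 would be expected by chance. The groups did not overlap in 559 genes that were higher and 319 that were lower, 6.31% of the tested genes against 2.86% by chance. Bdh1 did not pass when any 1 of the 8 libraries was left out, with log2 changes of 0.68 to 0.79, while Snora23 passed each time on its few low values. Neither passed with the replicate number as a block (adjusted p = 0.12 for Snora23 and 0.195 for Bdh1). Robust empirical Bayes called 9 genes higher, Dnmt3a among them (adjusted p = 0.0438). The adjusted p of Dnmt3a ranged from 0.0438 to 0.286 over its alternatives.

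Reported miR-29 targets were higher as a list, but the groups of libraries overlapped. Against the control mean, scrambled replicate 1 had a list median of 0.114, above anti-miR-29a replicates 1 and 3 at 0.058 and 0.107. Of 54 tested members 47 had a positive log2 difference, the median was 0.18, and the list rose against the other genes (camera, adjusted p = 0.000186; adjusted p = 0.564 with an estimated correlation). No member passed over all genes, and 5 passed when adjusted over the list alone. These were Dnmt3a, Serpinh1, Per1, Tet3 and Mmp2, the last one named here through the list of matrix proteases. Serpinh1 and Per1 had 0 matches to the miR-29 seed in the longest annotated 3' UTR, while Dnmt3a, Tet3 and Mmp2 had 5, 8 and 1. Serpinh1, a collagen chaperone, rose over the list alone from 6.26 ± 1.08 to 10.2 ± 2.02 FPKM, and Tet3, which oxidises methylated cytosine, from 5.08 ± 0.330 to 6.66 ± 0.564 FPKM. A subset chosen after seeing the data, the 18 members that no other list holds, had a median of 0.096 and did not pass by camera (unadjusted p = 0.254).

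Among DNA methylation genes the list rose by a median of 0.10 (camera, adjusted p = 0.049; adjusted p = 0.464 with an estimated correlation), with 16 of 22 members higher. Adjusted over the list alone, Dnmt3a, Tet3, Gadd45a and Gadd45b rose, the last 2 by 0.71 and 0.70 log2 units. Dnmt3a and Tet3 are also reported targets, and Gadd45b is also on the list of activity-regulated genes, so these lists are not independent. The call of the DNA methylation list ended in 6 of the 8 fits that left out 1 library, with scrambled replicates 1 and 3 the exceptions, and the median was 0.065 without scrambled replicate 2. Tet1 and Tet2 read 0.18 and 0.19 log2 units higher without passing (limma, adjusted p = 0.832 and 0.507; exact permutation p = 0.257 and 0.0286). Dnmt3b was below the filter at 0.177 ± 0.150 and 0.334 ± 0.133 FPKM.

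Collagens and other matrix genes were also higher as lists, but the 2 groups of libraries overlapped in both. Against the control mean, scrambled replicate 1 had the highest collagen median of the 8 libraries, 0.292, above the 0.069 to 0.232 of the anti-miR-29a libraries. For other matrix genes it stood at 0.153, above anti-miR-29a replicates 1 and 3 at 0.122 and 0.038. Collagen chains had a median of 0.17 with 19 of 28 members higher (camera, adjusted p = 0.0146; adjusted p = 0.61 with an estimated correlation), and Col26a1 alone passed over the list alone. Col4a1, Col4a2, Col1a1 and Col3a1 differed by 0.22, 0.26, 0.80 and 0.37 log2 units and none passed (limma, adjusted p = 0.49, 0.291, 0.386 and 0.767; exact permutation p = 0.0571, 0.0286, 0.114 and 0.486). Other matrix genes had a median of 0.13 with 27 of 33 higher (camera, adjusted p = 0.00876; adjusted p = 0.61 with an estimated correlation), and Fmod, a small proteoglycan gene, and Serpinh1 rose over the list alone, by 0.86 and 0.69 log2 units. The collagen call ended without scrambled replicate 2 or 3 or anti-miR-29a replicate 1, with medians of 0.095, 0.16 and 0.19, and the median was 0.27 without scrambled replicate 1. The call of other matrix genes ended without anti-miR-29a replicate 2 at 0.10, and their median was 0.22 without anti-miR-29a replicate 3. Matrix proteases and their inhibitors did not pass as a list (median 0.074, adjusted p = 0.0939; 0.12 and adjusted p = 0.0383 without anti-miR-29a replicate 1, but 0.022 and adjusted p = 0.143 without replicate 4 and 0.14 and adjusted p = 0.154 without replicate 3 of that group), though Mmp2, Timp4 and Serpine2 rose when adjusted over that list alone, by 1.17, 0.44 and 0.25 log2 units. Markers of meningeal and perivascular fibroblasts, which make matrix, moved with these lists. Their median was 0.29 with 13 of 17 higher (camera, adjusted p = 0.0106; adjusted p = 0.61 with an estimated correlation), and Ptgds, a prostaglandin synthase gene of the meninges, read 398.6 ± 82.1 and 607.1 ± 109.8 FPKM. The fibroblast call ended without scrambled replicate 2 or anti-miR-29a replicate 1, with medians of 0.10 and 0.28, and the median was 0.52 without anti-miR-29a replicate 3.

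Perineuronal net genes did not pass as a list (median -0.025, adjusted p = 0.416). Acan, the main net proteoglycan, was below the filter at 0.459 ± 0.0896 and 0.484 ± 0.132 FPKM. Bcan, Tnr, Cspg5 and Hapln1 differed by 0.18, -0.34, 0.16 and 0.31 log2 units and none passed. Pvalb, the marker of the interneurons that nets surround, read 75.7 ± 2.36 and 82.8 ± 5.41 FPKM (limma, adjusted p = 0.44; exact permutation p = 0.0286). The list of reported plasticity brakes had a median of -0.045 and missed the threshold (adjusted p = 0.0675), which it passed without scrambled replicate 3 or 4 at medians of -0.032 and -0.044, with Erbb4 at -0.39 and Epha4 at -0.23 log2 units as its members of smallest p.

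Sites for miR-29 were then counted in 3' UTRs. A match to the seed was present in 2074 of 13151 searched rows. No difference between these genes and the rest was detected by the test set in advance: the medians were 0.025 with a site and 0.026 without, a difference of -0.0012 log2 units (camera p = 0.728, two-sided; p = 0.849 with an estimated correlation). With the length and GC trend removed, an alternative chosen after seeing the data, the same unmatched difference was 0.043 and passed (camera p = 0.00114; p = 0.000671 with an estimated correlation). Before that removal the difference ranked 1 of 140 among the rearrangements of the site, whose median was -0.040 and whose highest other was -0.015 for TTGGTGC, a sequence overlapping the seed. Matched on 3' UTR length and expression the difference was 0.050 for any 7-base site and 0.083 for the 442 genes with an 8mer. Reported targets with a site, 43 genes, had a median of 0.18, and the 11 without one a median of 0.28.

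**Figure D2:**
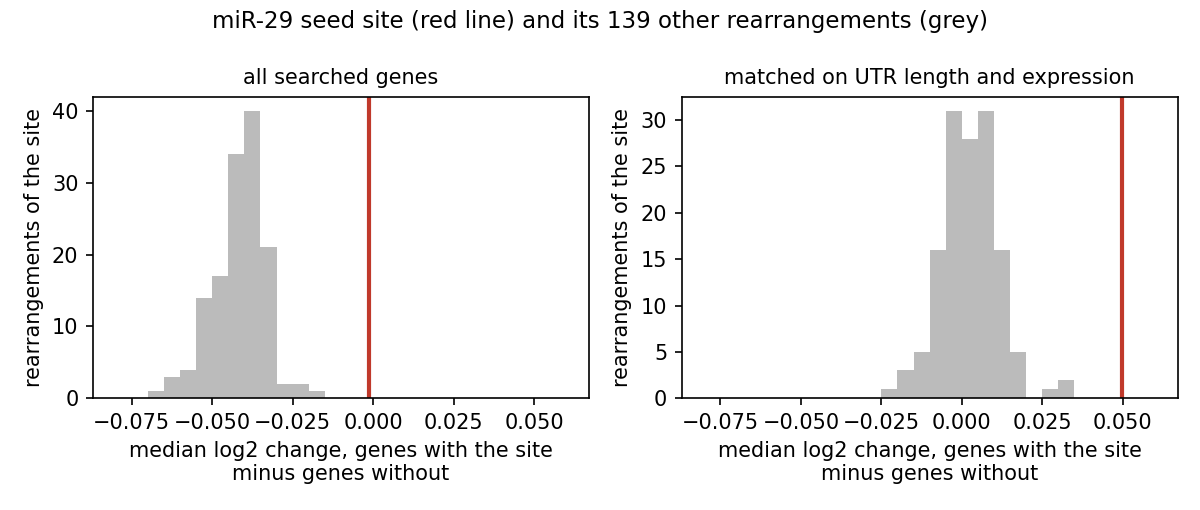
Histograms of the median log2 change of genes with a 7-base sequence minus genes without it, for the other rearrangements of the miR-29 seed site in grey and the seed site as a red line. The seed site stands at -0.0012 over all searched genes and at 0.050 after matching on 3' UTR length and expression, in both cases above the other rearrangements.

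Of the 9 genes with a 3' UTR among the 10 of smallest p, 6 held a site, compared with 15.8% of searched genes. Dnmt3a, on chromosome 12, had 5 matches in a 3' UTR of 6696 nt, including 8mers at 3911405 to 3911411 and at 3911474 to 3911480. Col26a1, on the minus strand of chromosome 5, had 4 matches in 1287 nt, and Bdh1 had its 8mer at 31457891 to 31457897 of chromosome 16. Ankrd13b, Tmem229b and Ccdc28b had 1 match each, while Dcakd, Dnajb5 and Sik1 had none. Tet3, on the minus strand of chromosome 6, had 8 matches in 5669 nt.

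**Figure D3:**
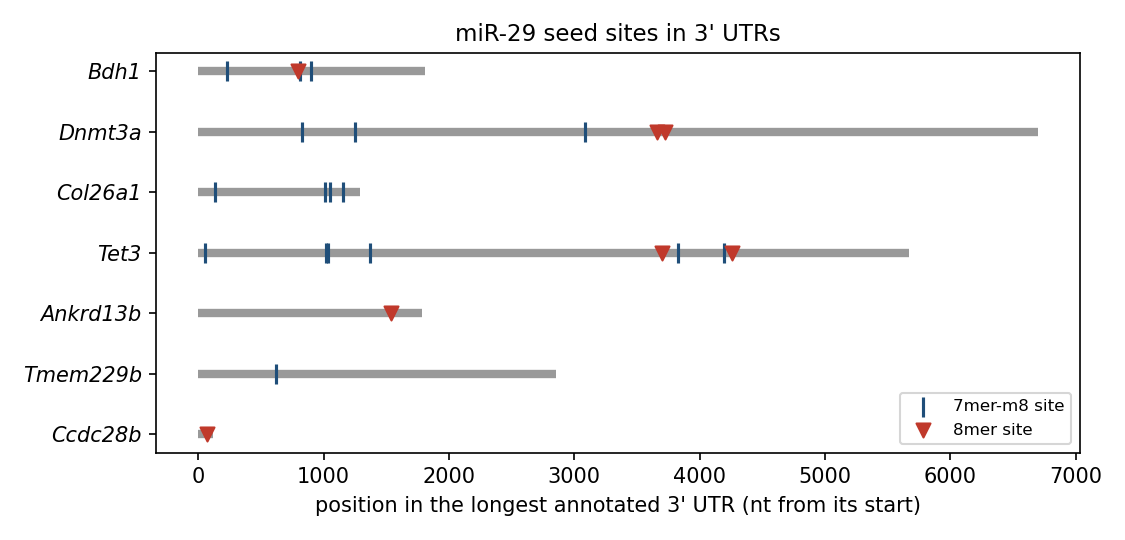
Matches to the miR-29 seed in the longest annotated 3' UTR of 7 genes, drawn to scale in nt from the start of the 3' UTR, with 7mer-m8 sites as blue bars and 8mer sites as red triangles. Tet3 has 8 matches, Dnmt3a 5, and Bdh1 and Col26a1 4 each.

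Activity-regulated genes, which neurons switch on after firing, had the largest median of the lists that passed. Of 30 members 27 were higher, by a median of 0.58 log2 units (camera, adjusted p = 7.97e-10; adjusted p = 0.464 with an estimated correlation). None passed over all genes, and 17 passed when adjusted over the list alone, all of them higher. Over the list alone Fosl2, an AP-1 subunit gene, rose from 3.6 ± 0.554 to 6.93 ± 1.05 FPKM, and Nr4a1, a nuclear receptor gene, from 67.7 ± 24.4 to 133.9 ± 12.9 FPKM. Sik1 and Per1 rose by 1.44 and 0.69 log2 units over the list alone. Scrambled replicate 1 stood apart at -0.45 from the control mean, whereas the other scrambled libraries stood at 0.17 to 0.26 and the anti-miR-29a libraries at 0.49 to 0.79. Without that library the median was 0.39, and the list was still called.

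**Figure D4:**
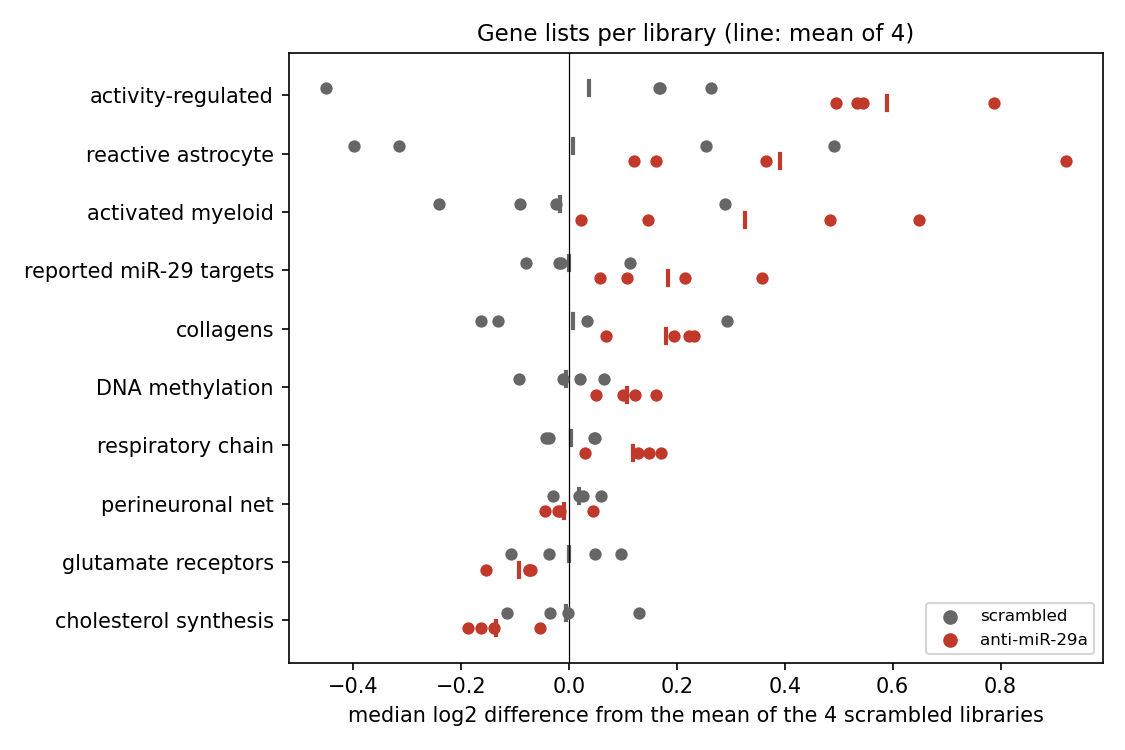
Median log2 difference of 10 gene lists from the mean of the 4 scrambled libraries, 1 point per library, scrambled in grey and anti-miR-29a in red, with a line at the mean of each group. Activity-regulated genes stand at 0.49 to 0.79 in the anti-miR-29a libraries, and scrambled replicate 1 at -0.45.

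Nuclear-encoded respiratory chain genes were higher as a list by a small amount, with a positive difference in 68 of 72 members and a median of 0.13 (camera, adjusted p = 4.24e-12; adjusted p = 0.464 with an estimated correlation). None passed over all genes and 8 passed when adjusted over the list alone, among them Atp5g1, Uqcrh, Ndufa4 and Ndufb11 with 0.28, 0.21, 0.15 and 0.23 log2 units. Ribosomal protein genes were higher by a median of 0.065 in 70 of 77 members (adjusted p = 0.000186; adjusted p = 0.728 with an estimated correlation). Glutamate receptor genes were lower in 19 of 24 members, with a median of -0.13 (adjusted p = 0.00107; adjusted p = 0.464 with an estimated correlation) and Grin2b at -0.64 and Grin2a at -0.38 log2 units, while Grm2, the member of smallest p, stood at 0.29. No member of this list passed over all genes or when adjusted over the list alone. GABA receptor genes had a median of -0.070 in 14 members (adjusted p = 0.00701; adjusted p = 0.564 with an estimated correlation), with Gabrb2 at -0.20. The ribosomal call ended without scrambled replicate 2 (median 0.020), the median was 0.10 without scrambled replicate 3, and the GABA receptor call ended without scrambled replicate 4 (median -0.047). Across all genes the change followed transcript length: the median was 0.12 for transcripts of 200 to 1000 nt and -0.064 above 6000 nt. With the trend in length and GC content removed, an alternative chosen after seeing the data, respiratory chain genes stood at 0.024 and ribosomal protein genes at -0.031, and neither passed. Glutamate receptor genes then stood at -0.085 (adjusted p = 0.0769) and GABA receptor genes at -0.063 (adjusted p = 0.15), so the GABA receptor median stayed near its value although its call ended.

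**Figure D5:**
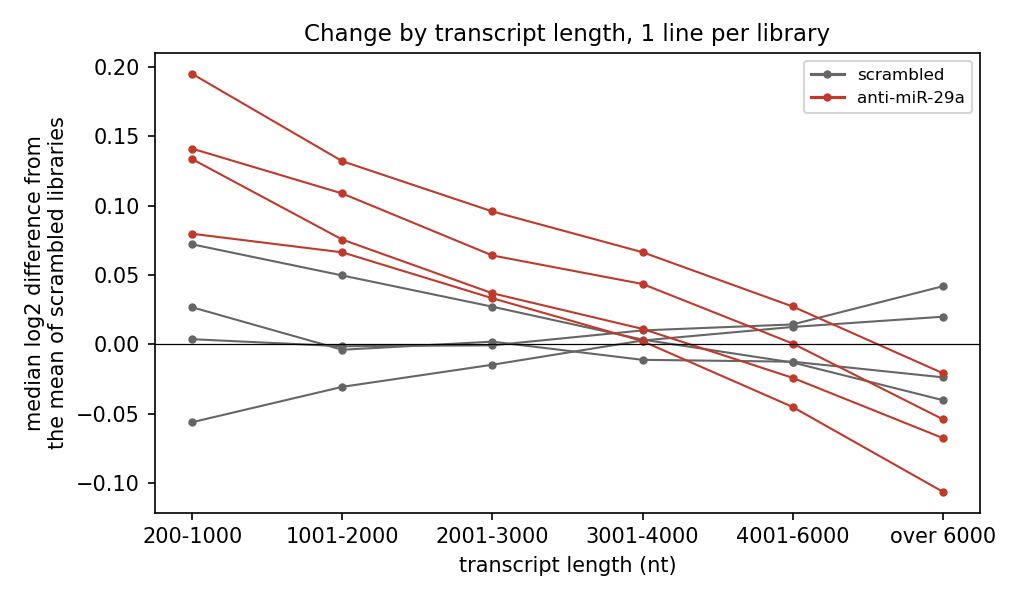
Median log2 difference from the mean of the scrambled libraries in 6 classes of transcript length, 1 line per library, scrambled in grey and anti-miR-29a in red. From the shortest to the longest class the change between groups goes from 0.12 to -0.064.

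Cholesterol synthesis genes fell, with a median of -0.17 and 17 of 22 members lower (camera, adjusted p = 4.16e-05; adjusted p = 0.464 with an estimated correlation). Stard4, a sterol carrier gene, fell over the list alone from 3.00 ± 0.464 to 1.48 ± 0.385 FPKM. Sc5d, Srebf2 and Hmgcs1 stood at -0.36, -0.22 and -0.21 log2 units without passing. The median of the list was -0.21 with the length and GC trend removed. Camera at the preset correlation then still called the list, but not with an estimated correlation (adjusted p = 0.463).

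Activated microglia and macrophage genes rose by a median of 0.33, with 22 of 24 higher (camera, adjusted p = 0.000574; adjusted p = 0.61 with an estimated correlation). Over the list alone Ms4a7, Gpnmb and Apoe rose, Apoe from 1183 ± 107 to 1583 ± 212 FPKM, though under quantile normalization its log2 difference was -0.057. Ms4a7 lay near the floor, at 0.097 ± 0.114 FPKM in scrambled libraries, with replicates 2 and 3 listed at 0, and 0.971 ± 0.424 in anti-miR-29a libraries. It met the filter only through the anti-miR-29a libraries, and its log2 difference ranged from 0.827 to 4.35 over its alternatives, so its size is not firm. The list median was 0.51 without scrambled replicate 1 and 0.16 without scrambled replicate 2, and it passed both times. Reactive astrocyte genes had a median of 0.41 and a positive difference in 16 of 17 members, and passed as a list although no member passed over all genes or when adjusted over the list alone (adjusted p = 0.00623; adjusted p = 0.61 with an estimated correlation), while Gfap, an intermediate filament gene, read 168.9 ± 70.1 and 274.8 ± 98.8 FPKM and did not pass (limma, adjusted p = 0.457; exact permutation p = 0.171). This call ended without scrambled replicate 2 or 4 or anti-miR-29a replicate 2, with medians of 0.30, 0.28 and 0.21. Anti-miR-29a replicate 2 had the highest value of the 8 libraries for both lists, 0.92 for reactive astrocyte and 0.65 for activated myeloid genes. Homeostatic microglia genes had a median of -0.060 and did not pass (adjusted p = 0.142), but did without scrambled replicate 3 or 4 or anti-miR-29a replicate 4, at -0.13, -0.12 and -0.095. Their direction is not settled, as the median was 0.089 without scrambled replicate 1 and 0.0090 without anti-miR-29a replicate 3. Oligodendrocyte markers had a median of -0.14 and passed (adjusted p = 0.0146; adjusted p = 0.741 with an estimated correlation), with Opalin at -0.64. That call ended without scrambled replicate 1, at a median of 0.027, and without anti-miR-29a replicate 4, at -0.079, and the median was -0.31 without scrambled replicate 4, so the direction of this list is not settled either. Scrambled replicate 4 had the lowest value of the 8 libraries, -0.47. Heat shock and unfolded protein genes rose by a median of 0.073 (adjusted p = 0.0237; adjusted p = 0.564 with an estimated correlation), with Sdf2l1 at 0.45. This call ended without scrambled replicate 1 or 4 or anti-miR-29a replicate 3, at medians of 0.087, 0.037 and 0.074, and the median was 0.12 without anti-miR-29a replicate 1. It ended too with the length and GC trend removed (median 0.035, adjusted p = 0.309), under quantile normalization (0.039, adjusted p = 0.146) and with a mean of at least 5 FPKM (0.073, adjusted p = 0.061).

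The remaining lists did not pass. Medians were 0.020 for excitatory neuron markers, 0.063 for interneuron markers and 0.062 for oligodendrocyte precursor markers, lists for which camera pointed the other way (adjusted p = 0.683, 0.984 and 0.985). Among precursor markers C1ql1 rose by 0.59 log2 units over the list alone. Astrocyte markers had a median of 0.020 (adjusted p = 0.573), 0.085 and passing without anti-miR-29a replicate 1, with Ntsr2 higher by 0.31 over the list alone. BH3-only and other apoptosis genes had a median of 0.12 (adjusted p = 0.17), where Cdkn1a and Bak1 rose over the list alone by 0.48 and 0.31. Medians were 0.15 for complement and antigen presentation genes, 0.23 for interferon genes, 0.11 for endothelial, 0.090 for mural and 0.48 for red cell genes (adjusted p = 0.1, 0.369, 0.369, 0.984 and 0.637). Scrambled replicate 1 stood highest of the scrambled libraries for complement (0.58), interferon (0.76) and endothelial genes (0.27), and without it these 3 lists passed at medians of 0.32, 0.50 and 0.17. Without scrambled replicate 4 they stood at 0.036, 0.061 and 0.073 (adjusted p = 0.913, 0.812 and 0.874). Chromatin modifiers had a median of -0.015 and a mean of 0.015, and medians were 0.062 for iron genes, 0.13 for cell division genes and -0.052 for markers of neighbouring regions (adjusted p = 0.683, 0.47, 0.683 and 0.339). Without scrambled replicate 2 the cell division median was 0.014, and red cell medians ranged from 0.27 to 0.85 with 1 library left out. Medians of the mural, precursor, astrocyte, chromatin, neighbouring region and perineuronal net lists changed sign in at least 1 such fit, none of them passing there. Of the 15 lists that passed by camera at the preset correlation, none passed with an estimated correlation, where the smallest adjusted p was 0.464, or with the directional test of fry. Fry's mixed test, for change in either direction, passed in 13 of all 33 lists, not all of them among those 15. The perineuronal net, chromatin, apoptosis, matrix protease, precursor and neighbouring region lists passed it without a call by camera. Several lists called by camera did not pass it, ribosomal protein and activated myeloid genes among them.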

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

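Of the tests below, that of 1 low control library and the count of splits were chosen only after the values had been seen, and removal of the length and GC trend was added after seeing the data. Over 346 groups of 4 libraries, counting each named gene and list in each group, 16 had 1 library far from the other 3, where chance at 1 in 20 gives 17.3, so the number of such libraries is no more than chance.

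In the scrambled group, replicate 1 lay above the others for Serping1 (7.76 against 3.55 to 4.02 FPKM) and Irf9 (6.01 against 3.05 to 3.31 FPKM) and below them for the activity-regulated list (-0.45 against 0.17 to 0.26). Replicate 2 lay high for Hbb-b2 (43.8 against 24.8 to 26.7 FPKM) and Rora (6.78 against 4.39 to 4.76 FPKM). Replicate 4 lay low for Neurod6 (21.9 against 23.8 to 24.2 FPKM) and high for Sdf2l1 (4.45 against 3.79 to 3.88 FPKM).

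In the anti-miR-29a group, replicate 1 lay high for Tet2 (9.25 against 7.58 to 7.79 FPKM), low for Fosl2 (5.37 against 7.25 to 7.62 FPKM) and low for the glutamate receptor list (-0.15 against -0.075 to -0.070). Replicate 2 lay high for Tnr (6.77 against 5.46 to 5.53 FPKM), Tfrc (12.2 against 10.97 to 11.1 FPKM) and the apoptosis list (0.35 against 0.051 to 0.071). Replicate 3 lay low for Col4a2 (9.56 against 10.4 to 10.6 FPKM), Lgals3bp (25.3 against 30.9 to 31.8 FPKM) and Igf2 (14.1 against 25.2 to 27.5 FPKM).

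The activity-regulated list was higher in the anti-miR-29a libraries with a median of 0.58, and no other of the 35 splits of the 8 libraries gave as large a value (1 of 35 with the real one, highest other 0.46). That is the smallest share that 35 splits can give, and splits were counted for all 33 lists. The count therefore argues against chance for this list but cannot exclude it. With a trend on transcript length and GC content removed, camera at the preset correlation still called the list. Camera with an estimated correlation did not (adjusted p = 0.312). The median was then 0.52, which argues against this trend as the whole cause of the rise. A single low control library may account for part of it: without scrambled replicate 1 the median was 0.39, between the bounds set for keeping and losing the pattern, so this stays open. A response of neurons to the block of miR-29a is a hypothesis, and handling of the animals before tissue was taken was not tested.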

How the results depend on the processing

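Leaving out short RNAs, removing the length and GC trend, the covariate for Y-linked expression and the list subset were chosen after seeing the data. Bdh1 lost its call in 12 of 20 alternatives and Snora23 in 1 of 17. The other 136 of the 138 named genes had no call to lose, and they gained one in 9 alternative values and reversed in 2. Where a result changed the cause was not tested, except that fewer libraries or more genes also lower power. Read depth was not used here, so what it limits is unknown.

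A pseudocount of 1 gave DNA methylation genes 0.0897 (adjusted p = 0.0518) and a seed difference of 7.69e-05. No filter left 0 genes higher by limma (1765 at an unadjusted p under 0.05) and collagens at 0.1257. A mean of at least 5 FPKM left 0 genes lower (1116), with other matrix 0.1889, DNA methylation 0.0875, stress 0.0734, apoptosis 0.1637 (now called), chromatin 0.001945, brakes 0.004463 and neighbouring regions 0.04851. Quantile normalization gave Nrgn -1.159, Apoe -0.05682, brakes -0.08446 (now called), excitatory -0.04283, astrocyte -0.01537, ribosomal 0.01074, stress 0.03887 and seed 0.002224. Median centring gave brakes -0.07396 and complement 0.1175 (both now called), excitatory -0.008913 and astrocyte -0.008953. Sample weights gave DNA methylation 0.1343, chromatin 0.003344, neighbouring regions 0.001489 and seed 0.004386. Robust empirical Bayes called 9 genes higher, with Dnmt3a at 0.6856 (adjusted p = 0.0438; range over its alternatives 0.0438 to 0.286). With the replicate number as a block limma called 0 genes higher and 0 lower (1476), and DNA methylation stood at 0.1039 (adjusted p = 0.0727). Short RNAs left out gave 0 and 0 (1507). Snora23 was not tested there, with trend removal or with a mean of at least 5 FPKM, because its transcript or its mean is too small, so these counts are not a lost call of that gene.

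Trend removal left 0 genes lower (1119) and 2 lists lower, with matrix proteases 0.1029 (now called), chromatin 0.0008294, glutamate receptors -0.08549, GABA receptors -0.06282, interneuron -0.003554, excitatory -0.007196, mural -0.00277, ribosomal -0.03084, respiratory chain 0.02368, stress 0.03476 and seed 0.04296. By camera that seed difference passed (unadjusted p = 0.00114). The Y-linked covariate gave 2 genes lower, collagens 0.1167, DNA methylation 0.1037, microglia -0.1042 (now called) and seed 0.002277. Non-overlap counted 559 genes higher and 319 lower, where chance gives 2.86%. The seed difference was 0.02332 for 8mers and -0.008934 for any site of at least 6 bases, and targets in no other list stood at 0.09637.

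With an estimated correlation camera called 0 lists higher and 0 lower, and fry likewise 0 and 0 by its directional test. Medians are unchanged by construction: targets 0.1827, collagens 0.167, other matrix 0.1279, DNA methylation 0.1039, activity 0.5817, glutamate receptors -0.1289, GABA receptors -0.06998, oligodendrocyte -0.1411, reactive astrocyte 0.4146, activated myeloid 0.3314, fibroblast 0.2903, ribosomal 0.06516, respiratory chain 0.1258, stress 0.0734 and cholesterol -0.1696.

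Leaving out 1 library at a time gave 0 to 2 genes higher, 1 to 2 lower (1220 to 1581 at an unadjusted p under 0.05) and 6 to 13 lists higher. Medians ranged over targets 0.1472 to 0.2343, activity 0.3864 to 0.653, respiratory chain 0.09603 to 0.146, cholesterol -0.2179 to -0.1213, glutamate receptors -0.1833 to -0.09281, activated myeloid 0.1604 to 0.513, cell division 0.0136 to 0.192, red cell 0.2725 to 0.8473, interneuron 0.02856 to 0.07178, excitatory 0.002853 to 0.03818, apoptosis 0.07245 to 0.1437, iron 0.0399 to 0.09248, astrocyte -0.01383 to 0.08537, chromatin -0.02318 to 0.01461, collagens 0.09549 to 0.2703, complement 0.03593 to 0.3208, DNA methylation 0.06498 to 0.1466, endothelial 0.0429 to 0.1653, fibroblast 0.1016 to 0.5151, GABA receptors -0.1047 to -0.04723, interferon 0.06127 to 0.5037, matrix proteases 0.02228 to 0.1408, microglia -0.1357 to 0.08862, mural -0.002161 to 0.2445, oligodendrocyte -0.3074 to 0.02727, precursor -0.00233 to 0.1035, other matrix 0.1023 to 0.221, neighbouring regions -0.09352 to 0.04922, perineuronal net -0.07027 to 0.02057, brakes -0.0633 to -0.03161, reactive astrocyte 0.2099 to 0.5598, ribosomal 0.02026 to 0.101, stress 0.03669 to 0.1166 and the seed difference -0.00767 to 0.005342. The seed rank was 1 in all 19 settings that gave one, and the matched difference 0.0438 to 0.0826.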

Other observations

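Of the tests below, the covariate for Y-linked expression, the fibroblast tests, the excess of targets over all genes, the seed rank outside the lists, the sites among the genes of smallest p and the counts of splits, except that of the matched seed difference, were chosen only after the results had been seen, and removal of the length and GC trend was added after seeing the data. Libraries carried transcripts of both sexes in 6 of 8 cases: Xist, expressed from the inactive X chromosome of females, read 7.59 to 33.1 FPKM in them together with the Y-linked Eif2s3y at 4.93 to 11.5 FPKM, both genes chosen after their values were seen. In scrambled replicate 1 and anti-miR-29a replicate 1 Xist read 0.016 and 0.11 FPKM and Eif2s3y 12.4 and 12.99 FPKM. With Y-linked expression as a covariate limma called 1 gene higher, which was Dnajb5 and not Bdh1, and 2 lower.

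Chance was set against each count. It cannot be excluded for the 2 genes called, as 5 of 35 splits called as many and the highest other called 3. Nor can it for the 15 lists, as 6 of 35 splits called as many and the highest other called 19. That split places scrambled replicate 1 with anti-miR-29a replicates 2, 3 and 4. For the 1492 genes at an unadjusted p under 0.05 no other split gave as many (1 of 35 with the real one, highest other 1038). This count was chosen after the results were seen, and 35 splits can give no smaller share than 1 of 35. It therefore argues against chance but cannot exclude it. With the length and GC trend removed the count was 1119, which was not set against other splits. Among the called lists not taken up elsewhere in these observations, chance cannot be excluded for any. A median as large came in 20 of 35 splits for oligodendrocyte markers (0.141, highest other 0.390), 13 for ribosomal proteins (0.0652, 0.119), 12 for other matrix genes (0.128, 0.285), 8 for fibroblast markers (0.290, 0.588), 6 for reactive astrocyte genes (0.415, 0.605) and 6 for stress genes (0.0734, 0.119). It came in 5 for activated myeloid genes (0.331, 0.538), 5 for collagens (0.167, 0.248), 5 for GABA receptors (0.0700, 0.109), 3 for DNA methylation genes (0.104, 0.114) and 2 for cholesterol genes (0.170, 0.184), all as sizes without sign.

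Reported miR-29 targets had a median of 0.18, and 3 of 35 splits gave one as large (highest other 0.21), so chance cannot be excluded for the list alone. A length and GC trend is argued against, as the median was 0.19 once it was removed. Camera at the preset correlation then still called the list, but not with an estimated correlation (adjusted p = 0.293). More fibroblasts in the tissue stay open for the 35 targets outside the collagen and matrix lists. Their median was 0.133, with a 95% bootstrap interval over genes of 0.0559 to 0.194, above the 0.026 of all genes. But 3 of 35 splits gave an excess as large, also for the 34 outside the protease and fibroblast lists. More fibroblasts stay open for the collagen targets too, at 0.37. Fibroblast markers that are neither targets nor matrix genes stood at 0.29 with an interval of -0.035 to 0.61. These 15 markers are too few to place their median. Dissection of more or less meninges may therefore contribute to the collagen values, with Ptgds, abundant in meninges, at 398.6 and 607.1 FPKM.

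Release of transcripts that carry a miR-29 site is the biological candidate, and the evidence is mixed. Over all searched genes no difference was detected, and 33 of 35 splits gave one as large. Matched on 3' UTR length and expression the difference was 0.050, which no other split reached (1 of 35, highest other 0.032), and among 12380 searched genes of no list it was 0.048 with rank 1 of 140 rearrangements, again unmatched by other splits (highest other 0.032). The rank by itself is weak, as 13 of 35 splits rank the site as close to an end after matching, and with the length and GC trend removed the unmatched difference went from -0.0012 to 0.043 (the matched one to 0.045), which no other split reached (highest other 0.032). Of the 9 searched genes among the 10 of smallest p, 6 held a site where matched draws held a mean of 1.75 (one-sided permutation p = 0.0014 over 10000 draws, chosen after 3 of them had been seen to hold sites), and a small release of miR-29 targets remains a hypothesis found and tested on the same libraries.

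Respiratory chain genes stood 0.126 higher and 2 of 35 splits gave a median as large (highest other 0.133), so chance cannot be excluded. Removing the length and GC trend took the median to 0.024. The removal would also take out a real change that follows transcript length, so it cannot tell a technical trend from a response. For glutamate receptors it went from -0.13 to -0.085 and the call ended (adjusted p = 0.0769), which is between the bounds set beforehand and leaves the trend open, and 2 of 35 splits gave a median as large (0.129, highest other 0.150), so chance cannot be excluded. Fold changes across genes had Spearman correlations of -0.295 with transcript length and 0.219 with GC content over 13800 genes, which are not independent replicates.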
